A study of Homo sapiens with 12 samples.

How the data were processed

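RNA from 12 samples of H1299 cells was sequenced, 6 kept under normoxia and 6 under hyperoxia for 24 h. Per the labels' protocols RNA was extracted with Trizol. The labels name an Illumina TruSeq kit in the extraction protocol, while the series' design text names removal of ribosomal RNA and a directional library kit of another maker, so the library type is not settled. Per the submitters' processing notes reads were counted with HTSeq 0.9.1 and normalised and tested with edgeR 3.16.5. The aligner, the gene annotation and the way TPM was computed are not given in the sources used here. The same notes list a mouse genome build, although every gene identifier is a human Ensembl one. No coordinates are printed for that reason, and genes are given by the symbol and identifier of the deposited table. Gene types came from GENCODE 29, which held 57365 of the identifiers.

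The deposited per-sample values are TPM, per the file headers, although the table is named as holding another unit; each sample's sum was nearly the same. The design had assumed that other unit, and the same test was used on TPM. The depth per sample is unknown, since TPM keeps none, and no counting intervals are given. The deposited table also holds the authors' group means in TPM, their fold change as a linear ratio, its log2, a p-value and an adjusted p-value per gene, and a call. The deposited numbers were checked against each other in every row. Apart from 78 genes, the authors' log2 fold change equalled the log2 of their fold change within 4.89e-08. Apart from 35 of those 78, the authors' group means equalled the mean of the 6 columns within 3.33e-06 TPM. In 3 of the 78 (ACTN4, HK2 and HIF1A) the adjusted p did not follow from the p. These rows stayed in the test, since the design was fixed before, and the totals of the comparison, and the counts of the lists where leaving them out changes a number that rose or fell, are also given without them. That check and its tolerances were set after the values were seen.

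Groups came from the treatment labels, and all 12 samples entered each fit. A gene was tested when its mean over the 12 samples was at least 1 TPM. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with the mean-variance trend on) on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjustment over 14520 genes and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes near the minimum. A fold minimum of 1.5 defined the larger changes. Gene lists were written before the data were examined and tested with limma's camera at a preset correlation between genes of 0.01, for the 32 lists with at least 3 tested members, with adjustment over the lists; camera with a correlation estimated per list and fry were run beside it. The lists cover NRF2 targets, antioxidant enzymes, HIF targets, glycolysis, p53 targets, stress and heat shock responses, cell cycle and histones, DNA repair, apoptosis, ferroptosis, iron, mitochondria, lipids, inflammation, matrix, YAP, MYC and AHR targets, ribosomal proteins, immediate early genes, metallothioneins, autophagy, the proteasome, noncoding RNAs, lung markers and markers of other cell types. Sample measures were compared by an exact two-sided permutation test over 924 arrangements, adjusted over 7 measures.

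Named genes followed a rule fixed before the data were examined. It took the 10 largest changes each way among adjusted genes with a proper symbol and no overlap between groups, up to 3 members of each list with the smallest p, and HMOX1, NQO1, TXNRD1, CA9, VEGFA, CDKN1A, HSPA5, DDIT3 and MYC whatever their values. A part of the rule on long noncoding RNAs was to apply only if the deposited file gave gene types, which it does not. Not every gene that the rule gives is named. Genes named beyond it are said to have been chosen after their values were seen. This holds for HIF1A, SLC38A1, HK1, HK2, BACH1, ENO1, PFKL and SLC16A3 too. It also holds for UGP2, ADD3, CDK5, SLC38A2, ACTN4, TPI1 and ZPR1, named for their deposited values.

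On simulated log2 values of the 14520 genes, with the means and spreads of this comparison and 200 genes changed, the limma step recovered 77% of changes of 0.5 and 94% of changes of 1 on the log2 scale, and 0.58% of its calls were false. Camera called none of the 32 lists on unchanged simulated values. Values of both simulations were drawn independently for each gene, so they do not test the calls of limma or camera where genes are correlated. Only 200 genes were changed, by 0.5 or 1, against 2516 called in the data. The shares recovered and false therefore do not carry over to those calls. The alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 TPM, 3 other scalings, eBayes without trend and with robust estimates, sample weights, an exact rank-sum test, a replicate block and leaving out each sample. Chosen after seeing the data were fits without the 78 genes, without normoxia replicates 4 to 6, and after rescaling to a common total without small RNAs, ribosomal RNA and the 78 genes. Tables were built with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures with matplotlib 3.10.9.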

Results

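H1299 is an established human cell line from a non-small cell lung carcinoma, and it lacks the tumour suppressor p53. Its RNA was sequenced after 24 h at 60% oxygen, 5% CO2 and 35% nitrogen (hyperoxia, n = 6) or under 21% oxygen, 5% CO2 and 74% nitrogen (normoxia, n = 6). The deposited values were TPM (transcript abundances scaled to a common total) for human Ensembl genes, and each sample's TPM summed to between 996138 and 998797. Between 14275 and 14635 genes reached 1 TPM in a sample. TPM keeps no sequencing depth, so the depth of each sample is unknown. The labels do not say whether the 6 samples of a group came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical.

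The comparison of the groups asks which transcripts of these lung cancer cells differ after a day of supplemental oxygen. Of 24 measured targets of the oxidative stress factor NRF2, 17 rose at 60% oxygen, 1 fell and 6 did not pass the test. The largest rise among them was that of HMOX1 (ENSG00000100292), the heme-degrading heme oxygenase 1, from 21.5 ± 1.53 TPM (SD, n = 6) to 95.3 ± 14.7 TPM (SD, n = 6). Its log2 fold change on the log2(TPM + 1) scale was 2.09 (SE 0.09, limma, Benjamini-Hochberg adjusted p = 7.27e-09). OSGIN1 (ENSG00000140961), an oxidative stress-induced growth inhibitor, rose by 2.04 (SE 0.07, limma, Benjamini-Hochberg adjusted p = 8.49e-10). Of 22 genes of the integrated stress response 16 fell, 2 rose and 4 did not pass the test (camera adjusted p = 2.61e-09; adjusted p = 0.281 with an estimated correlation). Among those that fell was CHAC1 (ENSG00000128965), a glutathione-degrading enzyme, from 72.5 ± 17.6 to 22.8 ± 2.79 TPM (SD, n = 6 each). Of 26 genes that peak in the G2 and M phases of the cell cycle 23 fell and 3 did not pass (camera adjusted p = 7.14e-27; adjusted p = 0.00525 with an estimated correlation).

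The NRF2 list holds targets of the transcription factor that drives antioxidant gene expression, of which 18 rose and 1 fell when adjusted over the list alone. The list lay above other genes in limma's camera test (adjusted p = 1.54e-15, and 0.00914 with an estimated correlation). FTL (ENSG00000087086), the ferritin light chain, went from 1480 ± 39.1 to 2937 ± 119 TPM (SD, n = 6 each; log2 fold change 0.99). The quinone reductase NQO1 (ENSG00000181019) went from 323 ± 9.62 to 614 ± 24.8 TPM (SD, n = 6 each; log2 fold change 0.92), and the thioredoxin reductase TXNRD1 (ENSG00000198431) from 295 ± 18.5 to 541.5 ± 22.8 TPM (log2 fold change 0.88). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 1.05 on the log2 scale (SE 0.05). It is named by the rule for the largest changes as applied, after the data were seen, without genes whose deposited values disagree. The member that fell was SLC7A11, the cystine importer, at -0.44 on the log2 scale (SE 0.11, limma, Benjamini-Hochberg adjusted p = 0.0172); it was chosen after its values were seen.

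**Figure D1:**
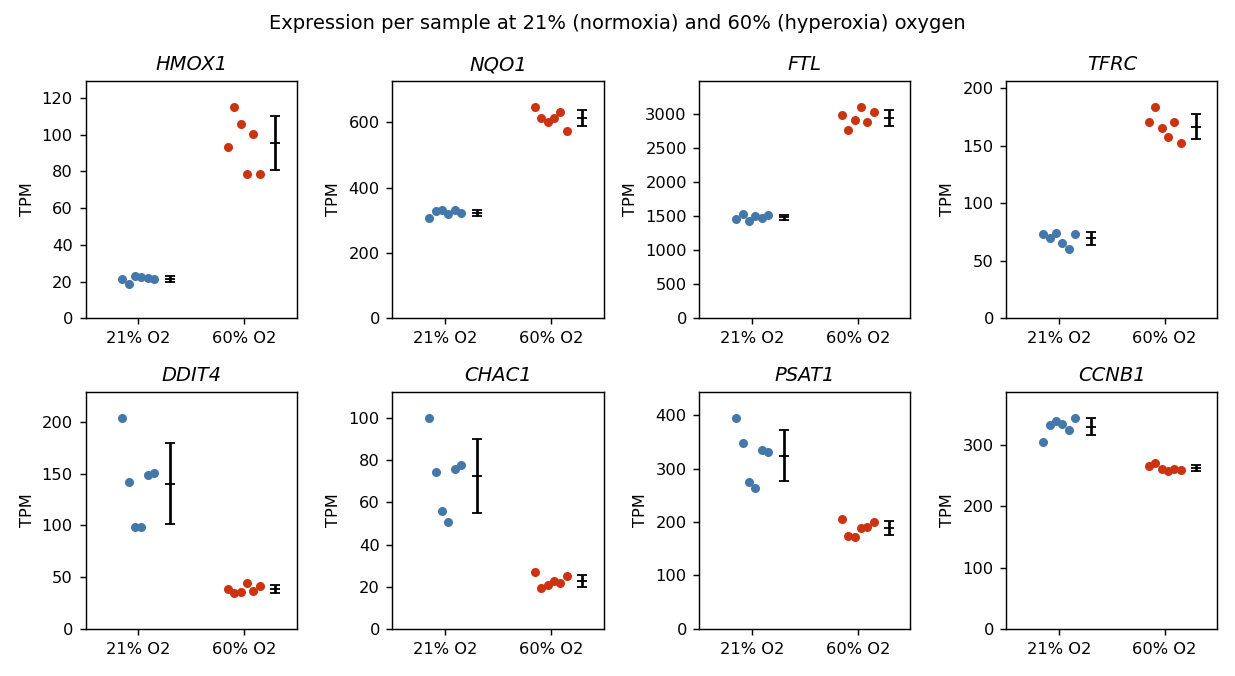
TPM of 8 genes (y axes, linear and starting at 0) in each of the 6 normoxia samples (21% oxygen, blue) and the 6 hyperoxia samples (60% oxygen, red); the black bar beside each group gives its mean and SD. In all 8 genes every hyperoxia sample lies on the same side of every normoxia sample: HMOX1 averaged 21.5 TPM in normoxia and 95.3 TPM in hyperoxia, and DDIT4 140.3 and 38.6 TPM.

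TFRC (ENSG00000072274), the transferrin receptor that brings iron into cells, rose from 69.4 ± 5.54 to 167 ± 10.9 TPM (SD, n = 6 each; log2 fold change 1.25), and the ferritin heavy chain FTH1 rose by 0.65 (SE 0.06). In the iron homeostasis list, 3 of 11 genes rose (TFRC, FTH1 and FTL, the latter 2 also in the NRF2 list), 1 fell and 7 did not pass (3 and 2 adjusted over the list alone; camera adjusted p = 0.131). Of 21 antioxidant enzymes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with the glutathione reductase GSR up by 0.76, thioredoxin TXN by 0.41 and the glutathione transferase GSTP1 by 0.35 on the log2 scale. Their camera adjusted p was 0.0391, and 0.185 with an estimated correlation; the call ended with median-of-ratios scaling (adjusted p = 0.0788). Among 18 ferroptosis regulators, genes of iron-dependent lipid peroxidation, 5 rose and 4 fell (also 5 and 4 adjusted over the list alone; camera adjusted p = 0.517), or 5 and 3 of 17 without SLC38A1, whose deposited values disagree. SAT1, a polyamine acetyltransferase, rose by 1.07 (SE 0.04), while GPX4, the lipid peroxide reductase, was lower at -0.18 (SE 0.06, limma, Benjamini-Hochberg adjusted p = 0.0408) and was chosen after its values were seen. The GPX4 call was lost in 14 alternatives, among them the exact rank-sum test (adjusted p = 0.151). Of 20 iron-sulfur cluster assembly genes, 4 rose and none fell (4 adjusted over the list alone; camera adjusted p = 0.242, and 0.0345 with no filter on low values), among them the scaffold gene ISCU at 0.27, ISCA1 at 0.26 and CIAPIN1 at 0.14 on the log2 scale. ISCA1 and CIAPIN1 lost their calls with median-of-ratios scaling (adjusted p = 0.0537 and 0.0705) and TMM factors (0.0514 and 0.0648), among other alternatives.

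Of 27 proteasome subunits, 21 rose and none fell (23 and 0 adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 2.23e-11; adjusted p = 0.185 with an estimated correlation). PSMA1 rose from 183 ± 6.24 to 230.1 ± 15.5 TPM, PSMC4 from 261 ± 9.04 to 322 ± 13.3 TPM and PSMD3 from 119.8 ± 8.58 to 148 ± 1.95 TPM (SD, n = 6 each). In the autophagy and lysosome list 6 of 22 genes rose, 1 fell and 15 did not pass (6 and 2 adjusted over the list alone; camera adjusted p = 0.0121, and 0.281 with an estimated correlation). SQSTM1 (ENSG00000161011), the autophagy receptor p62, rose from 254 ± 17.1 to 586 ± 28.6 TPM (SD, n = 6 each; log2 fold change 1.20), GABARAPL1 by 0.50 and the cathepsin gene CTSL by 0.31. Of 16 heat shock response genes 6 rose, none fell and 10 did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 0.0021, and 0.281 with an estimated correlation), including the co-chaperones BAG3 at 0.30, AHSA1 at 0.26 and DNAJA1 at 0.26.

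The integrated stress response list, which holds ATF4 targets of amino acid synthesis and transport, had 16 of 22 genes lower, 2 higher and 4 that did not pass (16 lower and 3 higher adjusted over the list alone; 15 of 21 lower without SLC38A2, whose deposited values disagree). Its median log2 fold change was -0.34 (camera adjusted p = 2.61e-09; adjusted p = 0.281 with an estimated correlation). CHAC1 fell by 1.60 on the log2 scale (SE 0.14, limma, Benjamini-Hochberg adjusted p = 8.65e-06), the amino acid transporter SLC7A5 by 0.72, its partner SLC3A2 by 0.49 and the stress-induced sestrin SESN2 by 0.81. PSAT1, an enzyme of serine synthesis, fell from 324 ± 48.1 to 188 ± 13.4 TPM (SD, n = 6 each), and ASNS, the asparagine synthetase, from 439 ± 80.6 to 269 ± 30.2 TPM. ASNS and ATF5 were chosen after their values were seen. SESN2 and PSAT1 came from the rule for the largest changes as applied, after the data were seen, without the disagreeing genes. The members that rose were PPP1R15A, which promotes recovery of translation, at 0.92, and the transcription factor ATF5 at 0.70. DDIT3, the stress factor CHOP, measured 47.5 ± 10.8 TPM in normoxia and 41.7 ± 4.43 TPM in hyperoxia (log2 fold change -0.16, SE 0.12, limma, Benjamini-Hochberg adjusted p = 0.41). In the unfolded protein response list of the endoplasmic reticulum 8 of 18 genes fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 1.35e-05, and 0.194 with an estimated correlation). The chaperone HSPA5 fell from 255 ± 16.0 to 194 ± 14.3 TPM (SD, n = 6 each), SDF2L1 by 0.41 and HERPUD1 by 0.48 on the log2 scale.

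Of the 26 G2/M genes none rose, and all 26 passed as lower when adjusted over the list alone. Without BUB1B, whose deposited values disagree, 22 of 25 fell. The median log2 fold change was -0.27. The mitotic kinase AURKA fell from 121.5 ± 2.91 to 94.1 ± 3.93 TPM and the mitotic cyclin CCNB1 from 330 ± 13.9 to 262 ± 4.60 TPM (SD, n = 6 each). PLK1, a further mitotic kinase, fell by 0.52 and the proliferation marker MKI67 by 0.41; both were chosen after their values were seen. The 33 DNA replication and G1/S genes went both ways, with 6 higher and 5 lower (9 and 6 adjusted over the list alone; camera adjusted p = 0.733). There the helicase subunits MCM6 and MCM7 fell by 0.30 and 0.28, while the cyclin CCNE2 rose by 0.42. The camera direction of this list was down although its median was 0.02 and its mean 0.02, since the test compares a list with the other genes. Of 15 replication-dependent histone genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.494), with H2AC11 at 0.40, H3C10 at 0.32 and H2AC20 at -0.60. H3C10 lost its call with no filter on low values (adjusted p = 0.0694) and H2AC20 under the exact rank-sum test (adjusted p = 0.0559).

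CDKN1A, the cell cycle inhibitor p21, rose from 25.9 ± 1.72 to 42.1 ± 2.80 TPM (SD, n = 6 each; log2 fold change 0.68). It was 1 of 3 genes that rose among 17 targets of p53, with the cytokine gene GDF15 at 1.20 and AEN at 0.23; 1 member fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.132, and 0.0147 with no filter on low values). Of 33 DNA repair genes 2 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.968), namely the nuclease EXO1 at 0.27 and PARP1 at 0.13. Of 24 apoptosis regulators 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.853). BID rose by 0.28 and CASP8 by 0.19, and the gene counted as lower, BAK1, has deposited values that disagree; without such genes 2 of 22 rose and none fell. CASP8 lost its call with median-of-ratios scaling (adjusted p = 0.0701), TMM factors (0.0688) and quantile normalisation (0.0782), among other alternatives. BID lost it under the exact rank-sum test (adjusted p = 0.0559). The DNA repair test pointed down at a median of 0.00 and a mean of 0.02, and the apoptosis test up at a median of 0.04 and a mean of -0.04.

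The 26 measured targets of HIF, the transcription factor of the response to low oxygen, had 6 genes higher, 2 lower and 18 that did not pass (10 and 2 adjusted over the list alone; camera adjusted p = 0.0967, and 0.0108 with no filter on low values). The glucose transporter SLC2A3 rose by 0.81 (SE 0.06) and the peptide hormone gene ADM by 0.76 (SE 0.07). DDIT4 (ENSG00000168209), an inhibitor of mTORC1 signalling, fell from 140.3 ± 39.3 to 38.6 ± 3.96 TPM (SD, n = 6 each; log2 fold change -1.80, SE 0.15). VEGFA, the vascular growth factor, measured 31.8 ± 3.58 and 30.0 ± 2.82 TPM (log2 fold change -0.08, SE 0.08, limma, Benjamini-Hochberg adjusted p = 0.528). The carbonic anhydrase gene CA9 was listed at 0 in all 12 samples. Of 17 glycolysis genes 3 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.00307, and 0.185 with an estimated correlation). For 10 of the 17 the deposited values disagree with each other; among the other 7 genes 2 rose and 1 fell, and camera without the disagreeing rows pointed up (adjusted p = 0.498).

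Among the 13 mRNAs encoded by mitochondrial DNA, 7 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 7.83e-04, and 0.37 with an estimated correlation). MT-CYB fell from 2651 ± 191 to 1835 ± 72.2 TPM and MT-CO3 from 5914 ± 291 to 4563 ± 115 TPM, while MT-ND1 rose from 1994 ± 108 to 2529 ± 86.2 TPM (SD, n = 6 each). Of 37 nuclear genes of the respiratory chain 7 rose and none fell (9 and 0 adjusted over the list alone), among them NDUFA8 at 0.24 and NDUFV2 at 0.21. Their camera adjusted p was 0.00397, and 0.281 with an estimated correlation; the call ended with median-of-ratios scaling (adjusted p = 0.0787). Of 38 cytosolic ribosomal protein genes 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 5.13e-06, and 0.281 with an estimated correlation). RPL3 fell by 0.25, RPS14 by 0.19 and RPS18 by 0.13; after quantile normalisation the list's camera adjusted p was 0.30 and that of RPS18 0.527. Among 22 targets of MYC, a driver of growth, 8 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 8.4e-05, and 0.281 with an estimated correlation), with the polyamine enzyme ODC1 at 0.49; without 3 disagreeing rows 7 rose and none fell.

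Lipid synthesis genes showed few single changes. Of 23 cholesterol biosynthesis genes only PMVK fell, by 0.29 on the log2 scale (1 adjusted over the list alone), and the list's median was -0.15 (camera adjusted p = 0.0021, and 0.543 with an estimated correlation). Of 11 fatty acid synthesis genes only ACACA passed, at -0.27 (none adjusted over the list alone; camera adjusted p = 0.0547). The ACACA call was lost in 13 alternatives (adjusted p = 0.119 with no filter on low values), and the list passed camera with median-of-ratios scaling (adjusted p = 0.0445), TMM factors (0.0443) and quantile normalisation (0.0496).

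Immediate early genes, which respond to signals within minutes, rose in part: of 15 tested 8 rose and 4 fell, or 8 and 3 of 14 without MYC, whose deposited values disagree (10 and 4 adjusted over the list alone; camera adjusted p = 0.00296, and 0.281 with an estimated correlation). FOS went from 1.18 ± 0.41 to 4.88 ± 1.01 TPM, FOSB from 0.47 ± 0.16 to 2.86 ± 1.15 TPM and EGR1 from 1.40 ± 0.16 to 3.50 ± 0.31 TPM (SD, n = 6 each), and the phosphatase gene DUSP1 rose by 1.10. With a minimum mean of 5 TPM, which removes several of these, the list's adjusted p was 0.231. Of 9 NF-kB and inflammatory genes RELB rose, by 0.32 (2 adjusted over the list alone; camera adjusted p = 0.0465, and 0.37 with an estimated correlation). The list's call ended with a minimum mean of 5 TPM (adjusted p = 0.102), without the mean-variance trend (0.0555) and with a replicate block (0.0714). It also ended in several fits that left out a single sample, among them hyperoxia replicate 2 (0.0993). Of 13 interferon-stimulated genes 2 rose, among them IFIT3 at 0.30 (2 adjusted over the list alone; camera adjusted p = 0.242). IFIT3 lost its call with no filter on low values (adjusted p = 0.0934) and under the exact rank-sum test (adjusted p = 0.0799), among other alternatives. Of 20 matrix and mesenchymal genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.733), with the transcription factor SNAI1 at 0.99 and THBS1 at 0.40. Of 14 YAP targets 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.622), with CCN2 at 0.44, NUAK2 at 0.38 and the receptor AXL at -0.29. Of 4 targets of the aryl hydrocarbon receptor NQO1 and TIPARP rose, the latter by 0.17 (2 adjusted over the list alone; camera adjusted p = 0.14). Among other alternatives, TIPARP lost its call with median-of-ratios scaling (adjusted p = 0.128), TMM factors (0.124) and quantile normalisation (0.132).

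The long noncoding RNA MALAT1 rose from 196 ± 16.4 to 343 ± 18.4 TPM (SD, n = 6 each; log2 fold change 0.81). It was the member that rose among 16 nuclear and small noncoding RNAs, and the spliceosomal RNA RNU5A-1 passed as lower, at 65.0 ± 73.4 and 3.96 ± 1.07 TPM (1 and 1 adjusted over the list alone; camera adjusted p = 0.122). RNU5A-1 was 1.65 TPM in normoxia replicate 1, below every hyperoxia sample, and 209.84 TPM in normoxia replicate 5. Its call was lost under the exact rank-sum test (adjusted p = 0.204), with no filter on low values (0.0545) and without normoxia replicates 4 to 6 (0.152), and the authors' deposited log2 fold change for it was 1.49, in the other direction. In normoxia replicates 4 to 6 5S ribosomal RNA took 0.303%, 0.735% and 0.23% of TPM against 0.0081% to 0.0695% in normoxia replicates 1 to 3 and 0.0001% to 0.0242% in hyperoxia. Of the metallothionein genes only 2 passed the level minimum, too few for camera, and MT1X fell by 0.25 (2 fell adjusted over the list alone). Of 15 lung epithelial markers only 3 passed the level minimum, the highest being the keratin gene KRT18 at a mean of 951 TPM. None of these 3 changed (camera adjusted p = 0.479, and none adjusted over the list alone). Of the markers of other cell types, CD68 was the only blood or immune gene tested (log2 fold change 0.00), the highest fibroblast marker was PDGFRB at 0.688 TPM and the highest endothelial marker PECAM1 at 0.252 TPM, means over all 12 samples.

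**Figure D2:**
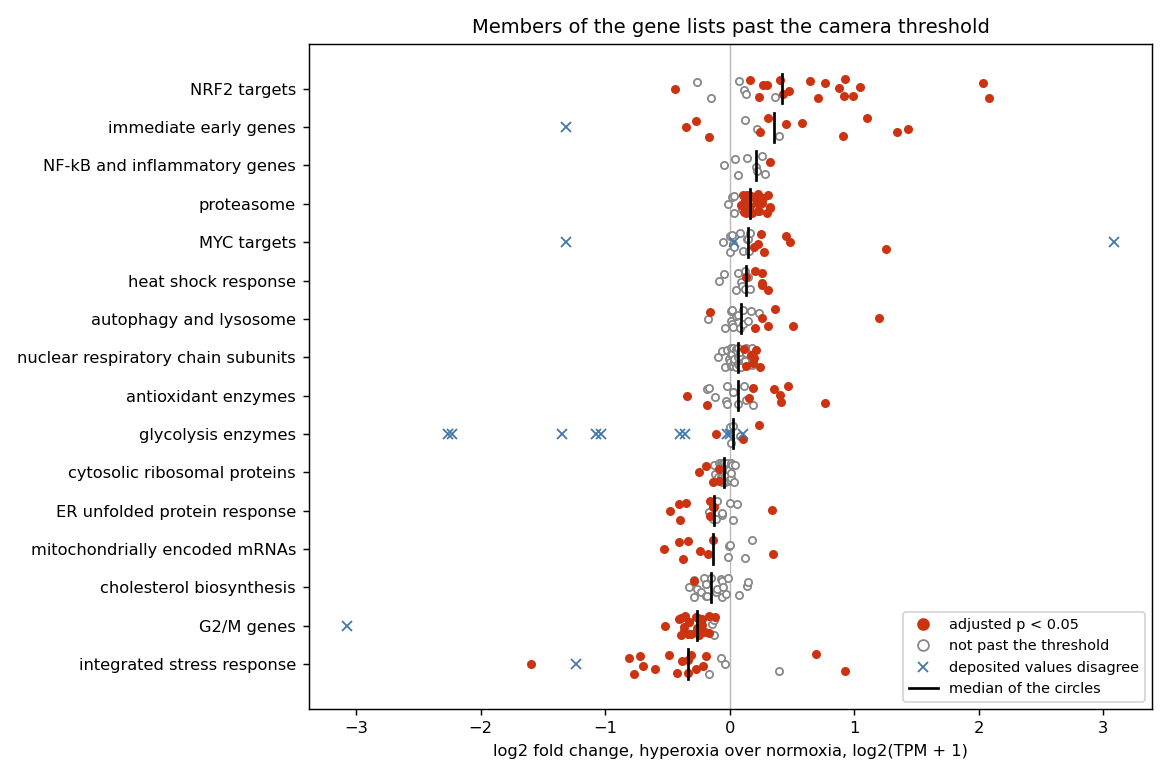
Log2 fold change of hyperoxia over normoxia, on the log2(TPM + 1) scale (x axis), for each tested member of the 16 gene lists past the camera threshold (rows). Filled circles passed an adjusted p of 0.05, open circles did not, crosses mark genes whose deposited values disagree, and black bars give the median of the circles. NRF2 targets lie mostly to the right (17 rose), G2/M genes to the left (23 fell), and 10 of the 17 glycolysis genes are crosses.

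In all, 14520 genes with a mean of at least 1 TPM were tested with limma, and 2516 changed at a Benjamini-Hochberg adjusted p under 0.05. Of these 1698 were higher and 818 lower in hyperoxia, and 153 changed at least 1.5-fold. TPM put the median gene at a log2 fold change of 0.03; scaling by median-of-ratios moved it to 0.00 and gave 1279 higher and 1277 lower genes, TMM factors gave 1305 and 1271, and quantile normalisation 1437 and 1208. Camera called 16 of 32 lists, and the NRF2 and G2/M lists were the 2 still called with an estimated correlation. Without normoxia replicates 4 to 6, left out after the data were seen, 1354 genes changed, 980 higher and 374 lower.

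The deposited table held 78 genes whose own values disagreed. In these the authors' log2 fold change was not the log2 of the authors' fold change (tolerance 0.0001), and in 35 of them the 6 hyperoxia columns did not average to the authors' deposited hyperoxia mean (tolerance 0.01 TPM). The sample values have at most 2 decimals in all other genes, while PFKL, UGP2 and PKM have values with 3, and ACTR8, ADD3 and CDK5 have a space after a value; all 6 are among the 78. Of the 20 genes with the largest changes under the fixed rule, 14 were among them: CAD, ABHD14B, CAMLG and CENPV, with higher hyperoxia columns, and all 10 with lower ones, ACOT7, BUB1B, SLC38A10, GPI, PFKM, ZSCAN21, AAAS, BAK1, ACTR8 and CEP41. In CAD (ENSG00000084774), which starts pyrimidine synthesis, the hyperoxia columns averaged 525 ± 173 TPM (SD, n = 6), and the authors' deposited table gave a mean of 65.0 TPM. In ACOT7 (ENSG00000097021), a thioesterase, the columns averaged 6.12 ± 4.98 TPM (SD, n = 6), and the authors' deposited mean was 96.1 TPM. MYC (ENSG00000136997) averaged 152 TPM in normoxia and 62.5 ± 18.5 TPM in the hyperoxia columns (SD, n = 6), against 188 TPM as the authors' deposited hyperoxia mean. Others of these 35 were the repressor BACH1, the glutamine transporter SLC38A1 and the glycolysis genes HK1, HK2 and SLC16A3. In all 35 the authors' log2 fold change was nearer to the ratio of the column means than to that of their own means. In the other 43 genes the columns averaged to the authors' means, but in 41 the authors' log2 fold change was more than 0.5 from the ratio of the column means. Among the 43 were the glycolysis genes PFKL, PKM and ENO1 (columns 2303 and 2307 TPM, authors' log2 fold change -2.01) and the oxygen-regulated factor HIF1A (columns 100.4 and 53.2 TPM, authors' log2 fold change -1.77). The difference was under 0.5 in PKM. In PKM, UGP2 and HIF1A the columns of the 2 groups did not overlap, yet the authors' deposited p was 0.931, 0.522 and 0.19. The deposited adjusted p of HIF1A, 0.00349, was below its p. TPI1 and ZPR1 also had columns without overlap, and their deposited p was under 0.05. Columns and deposited p thus disagree in PKM, UGP2 and HIF1A, and which of them is right was not tested. Counts of genes that rose or fell take these 78 genes by their columns, unless they are said to be left out. Without them 2469 genes changed, 1688 higher and 781 lower, and 118 at least 1.5-fold. The same rule, applied after the data were seen to the remaining genes, kept HMOX1, OSGIN1, FOS, FOSB, TFRC and GDF15 and added SQSTM1, DUSP1, SAT1 and GCLM. The lower genes it gave included DDIT4, CHAC1, SESN2, PSAT1, SLC7A5, the mitochondrial enzyme gene PCK2 at -0.91, the growth factor gene ANGPT4 at -0.80, the decoy receptor TNFRSF6B at -0.77 and PIGBOS1 at -0.73.

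**Figure D3:**
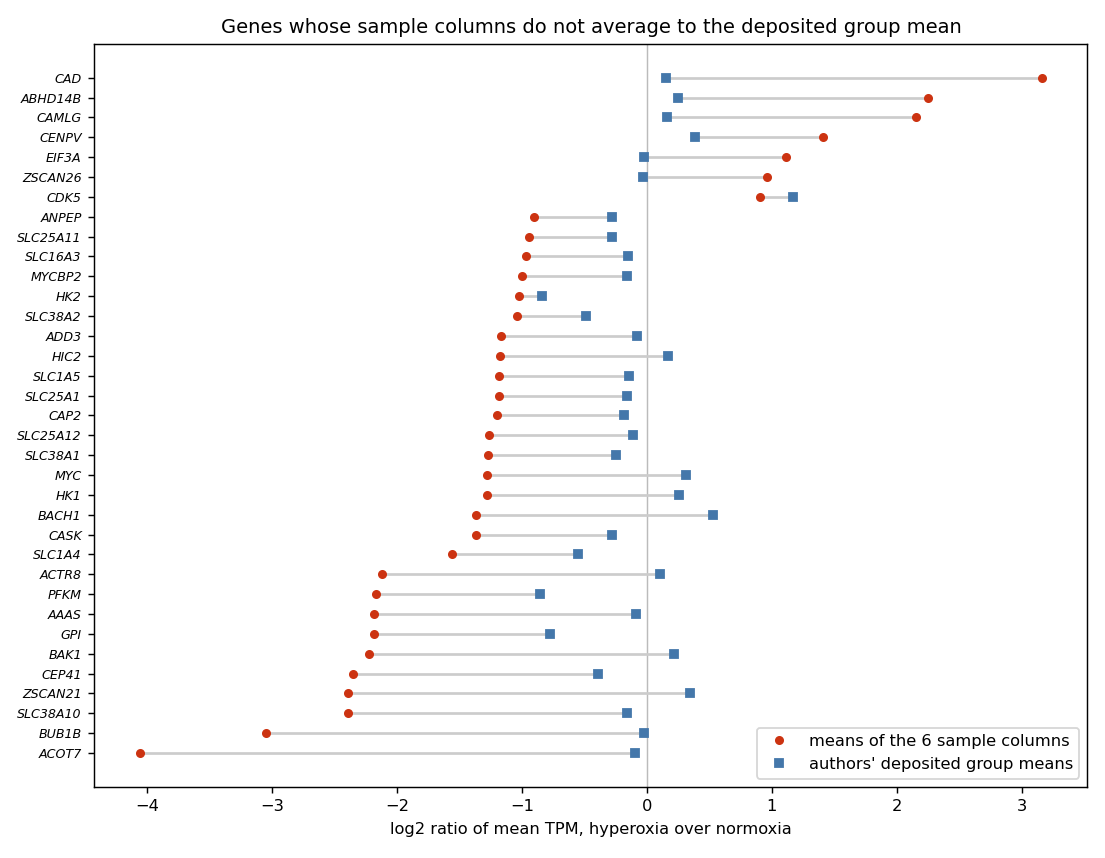
Log2 ratio of mean TPM, hyperoxia over normoxia (x axis), for the 35 genes (rows) whose sample columns do not average to the deposited group mean. Red circles are computed from the 6 sample columns of each group and blue squares from the authors' deposited group means; ACOT7 lies at -4.06 by its columns and at -0.09 by the authors' means.

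The authors' deposited table called 357 genes significant, 156 higher and 201 lower, of which 299 had an adjusted p of 1 in that table. Its adjusted p was under 0.05 for 4498 genes. Of the 14520 genes tested here 4357 had such a p, and 2235 of them were also among the 2516 called with limma, where 755 would be shared by chance. The sign was the same for 2233 and opposite for 2. Both sets of calls rest on the same 12 samples, so the overlap is not independent support.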

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

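All tests here were chosen after the results were seen, apart from the other ways to leave out 3 normoxia samples, whose prediction was written first. In 7 of 272 groups of 6 values 1 sample lay far from the other 5, where chance gives about 1 in 20 groups. In normoxia replicate 3 AAAS was 42.69 TPM (others 47.22 to 50.05) and BAG3 30.18 TPM (34.62 to 37.46), and in normoxia replicate 6 HK2 was 18.91 TPM (33.44 to 39.54). In hyperoxia replicate 6 MT-CO3 was 4337.81 TPM (4554.25 to 4649.31) and FTH1 762.62 TPM (652.33 to 676.05), and in hyperoxia replicate 3 CTSL was 92.55 TPM (82.08 to 85.07). Nuclear-encoded 45S, 28S and 18S ribosomal RNA took 0.1104% of TPM in hyperoxia replicate 2 (0.0037% to 0.0092% in the other hyperoxia samples). The deposited values of AAAS and HK2 disagree with each other.

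Among 100 of the 462 possible splits of the 12 samples, only the real split reached its counts. These were 2516 genes changed, 1698 higher, 818 lower and 153 changed at least 1.5-fold, and the highest other count was 1 for each. A share of 1 in 100 is the smallest this draw can give. The other splits mix samples of both groups, which widens the spread within groups and lowers their calls. They cannot tell oxygen from a batch or culture shared by a group. For gene lists past the camera threshold 1 split, again the real one, gave 16, and the highest other gave 15, so a number of lists near 16 also arises from splits with almost no single gene changed.

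In 35 genes the sample columns do not average to the deposited mean. A change in expression alone does not make columns differ from their own mean. In all other genes the columns averaged to the deposited means within 3.33e-06 TPM. In these 35 genes the columns are therefore not the values behind the deposited means. The tests asked whether the deposited p-values go with the columns, as after a change in expression, or with the deposited means. For the change in expression the deposited p was compared with those of the 20 other genes nearest in the ratio of the column means, of which a median of 35% had a smaller p. For the other explanation the 20 genes nearest in the ratio of the deposited means were used, and a median of 30% had a smaller p. These tests do not tell which values the p-values go with. Among other genes at 5 TPM or more, 92 had at least a 2-fold change of the column means. Their median deposited p was 0.202, so the genes compared often had a large ratio without a small p. Earlier forms of these tests were tried and replaced as uninformative (0 of 29 genes lay above the highest deposited p of other genes), and a further ranking by the limma p gave 80%. The SD of the hyperoxia columns lay above a high percentile of 200 genes of like level in 32 of the 35 genes, against 1 for normoxia, and 6 of the 78 disagreeing genes are the ones with an unusual number format; how the values arose was not tested, and the reads or counts behind them were not in the sources used here.

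The lower level of G2/M genes was weighed against other explanations. With TMM factors the list's median log2 fold change was -0.29 (24 of 26 genes fell). These factors moved the median of all genes from 0.0265 to 0.0001, so they could only move the list further down. TPM scaling thus does not make the direction, but this follows from that shift and the list's result adds no separate support. Without normoxia replicates 4 to 6 the median was -0.30 (21 fell), so these samples do not make it either. Fewer cycling cells overall could lower the DNA replication and G1/S list too, and its median was 0.0231 against -0.27 for G2/M. That list as a whole did not fall with G2/M. Its genes went both ways (6 higher, 5 lower), so its median cannot exclude fewer cycling cells. As a hypothesis found and tested on the same data, the values are consistent with a lower share of cells in G2 and M at 60% oxygen, or lower transcription of these genes; cell cycle phases were not measured in the sources used here.

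High 5S ribosomal RNA in normoxia replicates 4 to 6 could mark a library batch of these samples that makes the calls. Leaving them out gave 1354 genes changed. Of the 19 other ways to leave out 3 normoxia samples 15 gave as few (870 to 1807 over all ways). The lower count thus lies in the range that fewer samples give. It cannot exclude a batch, since calls depend on the spread within normoxia as well as on the number of samples. On the first principal component, the main axis of variation between samples, normoxia replicates 4 to 6 lay at -34.5 to -17.9. Normoxia replicates 1 to 3 lay at -6.9 to -2.5, and hyperoxia lay at 9.7 to 18.7. Small RNAs that take up TPM of other genes could shift the calls, but 97.8% of the genes changed (2409 of 2462) stayed past the threshold after rescaling without them. No biological explanation was tested, since the pattern lies within normoxia.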

How the results depend on the processing

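The fits without the disagreeing genes, without normoxia replicates 4 to 6 and after rescaling were chosen after the results were seen. No gene past the threshold in both the main setting and an alternative changed direction. Of the 124 named genes past the threshold 21 lost the call in at least 1 of up to 26 alternatives, 17 of them in alternatives other than leaving out samples or genes, and none reversed. AEN, CASP8, CIAPIN1, ISCA1 and TIPARP lost it under median-of-ratios and TMM scaling, and RPS18 under quantile normalisation. BID, THBS1, MT1X, H2AC20, RNU5A-1, HK2, GPX4, ACACA and IFIT3 lost it under the rank-sum test, and H3C10 and BACH1 with no filter, among other alternatives for some of them. CENPV, TNFRSF6B and SLC38A1 lost it without normoxia replicates 4 to 6. Of the 16 lists called, 10 were called in every camera alternative with the preset correlation.

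The main setting gave 2516 genes changed, 1698 higher, 818 lower, 153 changed at least 1.5-fold and 16 lists. A pseudocount of 0.1 gave 234 genes changed at least 1.5-fold, as it shrinks low genes less. Lower genes numbered 1277 with median-of-ratios scaling, 1271 with TMM factors and 515 with the exact rank-sum test; the scalings move the centre of the fold changes, and for the rank-sum test the cause was not tested. Without normoxia replicates 4 to 6 there were 1354 genes changed, 980 higher and 374 lower, with fewer samples. Leaving out 1 sample at a time gave 1958 to 2452 genes changed, 1317 to 1563 higher, 602 to 937 lower, 140 to 162 changed at least 1.5-fold and 14 to 17 lists. With a correlation estimated per list 2 lists were called, also 2 without the disagreeing genes, and fry called 22 one-way and 29 in its mixed form, which counts changes both ways.

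The glycolysis list reversed: its median log2 fold change was 0.0289 without the disagreeing genes (camera adjusted p = 0.498; 0.547 with an estimated correlation) and 0.0261 after rescaling (camera adjusted p = 0.535), since 10 of its 17 genes are left out there.

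With the replicate number as a block (replicate block) 2545 genes changed, and of the named genes IFIT3 (adjusted p = 0.0612) and GPX4 (0.0646) lost their call. Of the lists, antioxidant enzymes (0.0601) and NF-kB genes (0.0714) lost it, fatty acid synthesis (0.0242) gained it, and no other named gene or list changed its call. Same-numbered samples correlated at -0.117 to 0.0169 in their deviations from the group means, and no sample correlated best with its own number, so the numbers were not used to pair samples. The alternative on raw counts could not be run, as the file holds none, and the exact rank-sum test gives no camera value. TPM keeps no depth, so what depth limits is unknown.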

Other observations

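Gene Ontology terms were tested after the results were seen, without the disagreeing genes, and so were the genes named here. Of 2119 terms with 10 to 200 genes, 28 passed camera with the preset correlation, 17 higher and 11 lower, and none with an estimated correlation (smallest adjusted p = 1). For rRNA processing 50 of 176 genes rose and 2 fell (camera adjusted p = 2.35e-04), among them NOB1 at 0.39, NOP2 at 0.39 and NOLC1 at 0.46 on the log2 scale. For mitochondrial translational elongation 28 of 93 rose and 2 fell (adjusted p = 0.0151), with MRPL9 at 0.27 and MRPS5 at 0.28. For cellular iron ion homeostasis 14 of 46 rose and none fell (adjusted p = 0.0022), and for phagosome acidification 8 of 19 rose and none fell (adjusted p = 0.0452). The proton pump genes ATP6V1E1 and ATP6V1F rose by 0.37 and 0.27, and the transporter ABCB6 by 0.59. For mitotic sister chromatid segregation 13 of 37 genes fell and none rose (adjusted p = 2.35e-04).

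The mitochondrial ribosomal RNAs were higher in TPM in hyperoxia while most mitochondrial mRNAs that changed fell. The series' design text names removal of ribosomal RNA. If it was done, uneven removal cannot be told apart from a change of these RNAs. MT-RNR1 went from 635 ± 112 to 925 ± 81.0 TPM (SD, n = 6 each; adjusted p = 0.00265) and MT-RNR2 from 1310 ± 62.7 to 1882 ± 154 TPM (adjusted p = 2.22e-05). Within normoxia MT-RNR1 was 521.49 to 554.52 TPM in replicates 1 to 3 and 716.0 to 763.99 TPM in replicates 4 to 6, the samples with high 5S ribosomal RNA; without replicates 4 to 6 the log2 fold change was 0.79 for MT-RNR1 (adjusted p = 1.84e-04) and 0.58 for MT-RNR2 (adjusted p = 6.7e-04). Together they took 0.195% of TPM in normoxia (0.175% to 0.184% in replicates 1 to 3, 0.206% to 0.215% in replicates 4 to 6) and 0.281% in hyperoxia (exact permutation p = 0.00216, the smallest possible here; adjusted p = 0.0151 over 7 measures). The 5S ribosomal RNA share was 0.227% and 0.00813% (adjusted p = 0.0532), and the other measures had adjusted p of 0.116 or more. The replication-dependent histone gene H4C3, whose mRNA has no poly(A) tail, averaged 1.48 TPM in normoxia and 1.56 TPM in hyperoxia (adjusted p = 0.799).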
